A study of Gallus gallus with 28 samples.

How the data were processed

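The series holds 28 samples from 10-day-old Cobb broiler chicks, a fast-growing meat strain of Gallus gallus. Of these, 18 are RNA libraries of the anterior preoptic hypothalamus, the brain region that regulates body temperature, and 10 are reduced-representation bisulfite (RRBS) libraries, an assay of DNA methylation. Only the RNA libraries are analysed here. The 10 methylation libraries, 5 per parental group, are not analysed here. Per the protocols in the labels of the methylation samples, embryonic heat conditioning of the parents meant incubation at 39.5 °C for 12 h per day on embryonic days 7 to 16, against 37.8 °C in control eggs. The chicks studied here are the offspring of such birds and were not conditioned themselves. They were taken unchallenged (t0), 6 h after a move from 30 °C to 36 °C, or 6 h after an injection of lipopolysaccharide (LPS, a bacterial cell wall component that sets off an innate immune response) into the third ventricle of the brain. The 6 groups of RNA libraries hold 3 libraries each. The labels number them 1 to 4, with 1 number absent from each group, for a reason not given. Library numbers below are the replicate numbers of the titles. No group was kept for 6 h without a challenge or injected without LPS. Heat therefore cannot be told apart from handling and elapsed time, nor LPS from these and the injection. Genes raised or lowered by a challenge are those that differed from t0.

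Per the labels' protocols, RNA was extracted with TRI reagent, 15 ng went into bulk MARS-seq libraries, which read the 3′ ends of polyadenylated transcripts, and single reads of 100 bases were sequenced. The tools listed from the submitters' processing notes are cutadapt, STAR, HTSeq and DESeq2, with the galGal5 build. Their versions and settings, the collapse of reads sharing a molecular identifier, the use of strand in counting and the filter behind the listed genes are not given in the sources used here. With 3′ libraries, a gene's value depends on an annotated 3′ end, and paralogs and overlapping genes could not be judged without gene models.

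The deposited table lists 11207 Ensembl gene identifiers. Per the file headers, one block of columns holds raw counts per gene, and a second block holds the authors' normalized signal for the same libraries. Raw counts were whole numbers that summed to between 828424 and 4589179 per library, and each normalized column was the raw column divided by 1 constant. The authors' factors were nearly proportional to the median-ratio factors of the counts. Over all 18 libraries the latter divided by the former gave 0.582 to 0.604. The counts were tested. The normalized signal served only for a filter and for an alternative set of factors.

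The table pairs no identifier with a gene name, and the reference table of 25635 genes of the GRCg7b assembly given for this work has an empty column for Ensembl identifiers, so that 0 of the 11207 identifiers could be paired with it. Gene names are therefore not used here. The 29 gene lists fixed before the data were examined (heat shock chaperones, cytokines, hypothalamic peptides, cell type markers and signs of RNA quality among them) could not be applied, and neither the cell composition nor the RNA quality of the libraries was assessed. The rule fixed for named genes asked for gene symbols, for up to 6 rising and 6 falling genes in each comparison, and for a list of genes always given. Without symbols the rule could not be followed. A reduced form was applied to the LPS response of the non-conditioned lineage, with these conditions kept: adjusted p under 0.05, a mean normalized value of at least 10 over the libraries compared, and no overlap between the 2 groups of 3 libraries. The 2 genes with the largest rise and the 2 with the largest fall are given by identifier. Genes behind counts of 5 or fewer in the edgeR test of all 18 libraries are also given by identifier, but not those behind the counts of alternatives. They were chosen after their values were seen, as was a gene with the smallest adjusted p in the difference of the heat response.

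Counts were normalized by TMM and tested with edgeR 4.0.16 (quasi-likelihood fit and test) in R 4.3.3, in 1 group-means model over all 18 libraries, after filtering low genes by group (7921 genes kept, holding 99.5% of the counts). P-values were adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. Counts at an unadjusted p under 0.05 are given for scale. With no change at all, about a share of 0.05 of the 7921 genes would reach it. Standard errors were taken as the log2 fold change divided by the square root of the F statistic. Levels are given as CPM, the counts scaled to a common library size by the cpm function of edgeR with TMM factors, as mean ± SD over 3 libraries. Gene sets were tested by the exact permutation of parental labels inside t0 and inside the challenge (400 arrangements, 2-sided), and by fry from limma 3.58.1. Within 1 condition, 3 libraries against 3 were compared by an exact permutation test, which cannot go below 0.1. The gene sets were taken from the average of both lineages' responses, a contrast added after the data were seen, so that the difference between lineages did not pick them. Principal components were computed from the 1000 most variable genes on log2 CPM with a prior count of 3. Figures were drawn with matplotlib 3.10.9.

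The comparisons, fixed at the start, were heat and LPS each against t0 in both lineages, conditioned against non-conditioned parents within each condition, and the difference of each response between lineages. The alternatives fixed at the same time were DESeq2 1.42.0, its size factors within edgeR, no filter, a stricter filter (mean normalized value of at least 20), a fit to the compared groups only, the replicate number as a block, voom with library quality weights, and leaving out each library in turn. Thinning to the shallowest total, the deposited factors, removal of 2 t0 libraries and a common t0 control were added after the data were seen.

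The test was checked on simulated counts drawn from the real means, dispersions and library sizes of the 7921 genes, with 200 genes changed per comparison. Where few genes change, the adjusted threshold is stricter, so that fewer of them would be recovered than given here. For LPS against t0 in the non-conditioned lineage, 14.9% of 1.5-fold, 53.7% of 2-fold and 87.9% of 4-fold changes were recovered. For heat against t0 in the same lineage these were 7.46%, 46.3% and 72.7%, and for conditioned against non-conditioned parents at t0 they were 5.97%, 38.8% and 75.8%. The difference of the heat response between lineages was the least sensitive, with 42.4% of 4-fold changes recovered, against 63.6% for the difference of the LPS response. Unchanged genes made up 5 of 89 calls for heat and 9 of 113 for LPS in the non-conditioned lineage. In the conditioned lineage they made up 7 of 88 and 4 of 99. Between lineages they were 3 of 83 at t0, 12 of 111 under heat and 6 of 97 under LPS. For the differences of the heat and LPS response they were 3 of 41 and 7 of 65. This share lay above the one set by the adjusted threshold except for LPS in the conditioned lineage and between lineages at t0. Replicate libraries of every group differed by more than sampling noise, with a chi-square per degree of freedom between 3.92 and 18.8, so that none of the libraries was a copy of another of its group; pairs from different groups were not compared in this way. The labels do not say whether a library holds 1 bird or several, and give no sex, pen or library batch, so that p-values measure the spread between these libraries.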

Results

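Gene expression was measured in the anterior preoptic hypothalamus of 10-day-old chicks whose parents had or had not been heat conditioned as embryos (conditioned and non-conditioned lineage, below). Each lineage had 3 libraries at t0, 3 after 6 h of heat at 36 °C and 3 at 6 h after LPS. The genes are given by Ensembl identifier, since the table pairs no identifier with a name. Total counts per library ran from 828424 to 4589179, with between 9501 and 10967 genes counted. At t0 depth and lineage went together: the 3 libraries of the non-conditioned lineage held 3379626 to 4589179 counts and those of the conditioned lineage 828424 to 1422688, a 3.58-fold difference in means. Under heat and LPS the totals of the lineages overlapped. The 10 most abundant genes took between 10.7% and 16.8% of the counts.

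LPS separated the libraries on the first principal component, which held 27.1% of the variance. The 6 LPS libraries had scores of 16.8 or more and the 12 t0 and heat libraries scores below 0. Heat and t0 libraries were not separated on it. On the second component (17.4% of the variance), t0 libraries 2 and 3 of the conditioned lineage lay at -20.5 and -33.3, while the other t0 libraries lay at 3.41 or more.

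**Figure D1:**
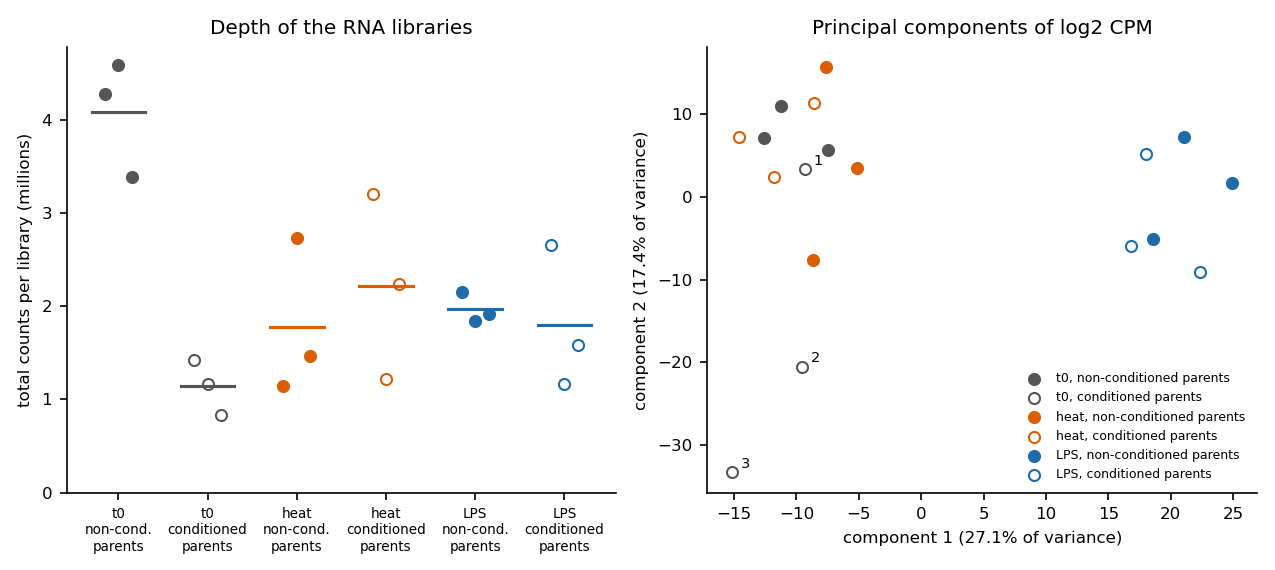
Left, total counts per library for the 6 groups (points, libraries; lines, means of 3). Right, the 18 libraries on the first 2 principal components of log2 CPM, with replicate numbers beside the t0 libraries of the conditioned lineage; LPS libraries lie at 16.8 or more on component 1, and t0 libraries 2 and 3 of the conditioned lineage at -20.5 and -33.3 on component 2.

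The response to heat in the non-conditioned lineage asks what differs from t0 after 6 h at 36 °C in chicks without conditioned parents. Heat raised 4 genes and lowered 0. ENSGALG00000023818.4 went from 79.3 ± 10.0 CPM at t0 to 428 ± 156 under heat (SD, n = 3 each), a log2 fold change of 2.43 ± 0.31 (SE), with an edgeR adjusted p of 0.00066. ENSGALG00000011715.5 rose from 178 ± 32.1 to 614 ± 166 CPM (log2 fold change 1.78 ± 0.22, edgeR adjusted p = 0.00066). ENSGALG00000009433.6 rose from 58.9 ± 8.11 to 151 ± 38.4 CPM, by 1.35 ± 0.21 on the log2 scale (edgeR adjusted p = 0.00603). ENSGALG00000033789.2, the most abundant of them, rose from 407 ± 38.1 to 799 ± 33.6 CPM, close to the log2 fold change of 0.98 ± 0.12 that the model gave (edgeR adjusted p = 0.00066). In all 4 genes every heated library lay above every t0 library. Chance separates 3 libraries from 3, in one direction or the other, in 10% of genes. Against the t0 libraries of the conditioned lineage the same heated libraries were higher by 1.10 to 1.82 (edgeR adjusted p at most 0.0252). These heated libraries had picked the 4 genes, so this comparison changes the control alone and is no independent test. A further gene, ENSGALG00000033212.2, had a log2 fold change of 0.80 ± 0.16 with an edgeR adjusted p of 0.068, outside the threshold. It passed with DESeq2 (adjusted p = 0.00042), voom (adjusted p = 0.00794) and the replicate block (edgeR adjusted p = 0.0301), within a range of 0.00042 to 0.381 over its alternatives. DESeq2 called 27 genes in this comparison, the 4 among them, and voom with quality weights called 13. ENSGALG00000009433.6 lost its call when only the compared groups were fitted (edgeR adjusted p = 0.0927), without t0 library 2 (0.0744) or without heated library 1 (0.0687), within a range of 1.7e-06 to 0.0927 over its alternatives.

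**Figure D2:**
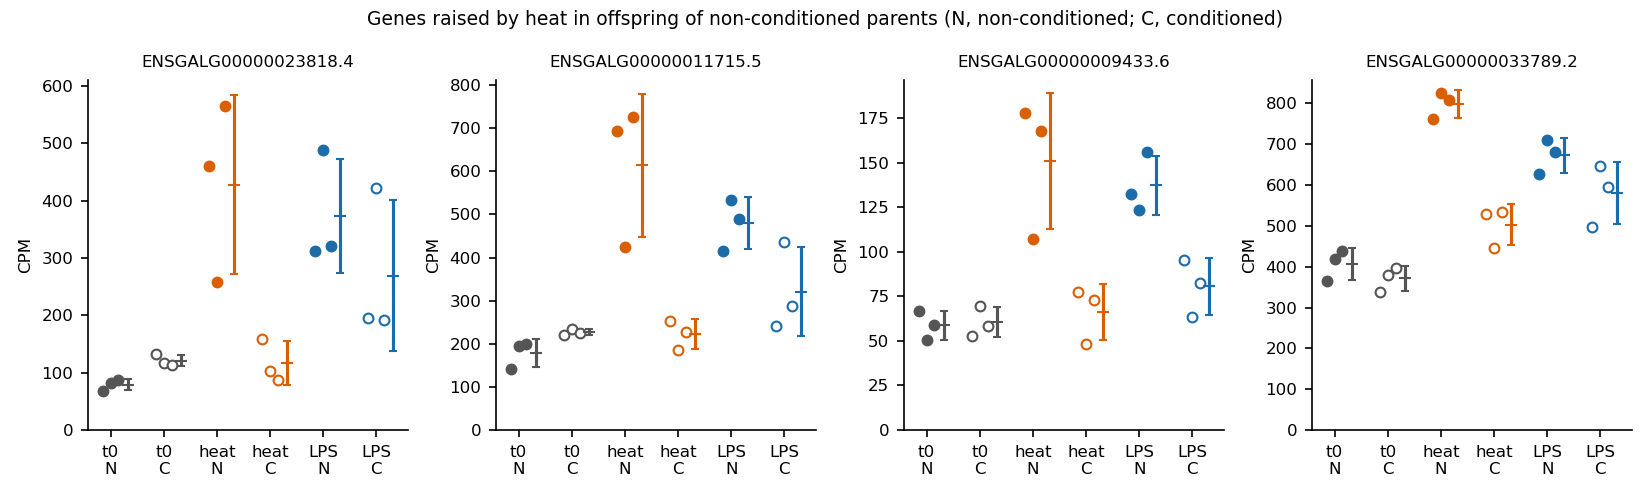
Level in CPM of the 4 genes raised by heat in the non-conditioned lineage, per library (points) with mean ± SD of 3 libraries (bars), for t0, heat and LPS in the non-conditioned (N) and conditioned (C) lineage. Every heated library of the non-conditioned lineage lies above every heated library of the conditioned lineage in all 4 genes, as in ENSGALG00000011715.5 with 614 ± 166 against 222 ± 34.6 CPM.

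In the conditioned lineage the same challenge gave 0 calls with edgeR (1034 genes at an unadjusted p under 0.05, smallest adjusted p 0.21). The 4 genes raised in the other lineage had log2 fold changes near 0 or small. For ENSGALG00000011715.5 heat and t0 stood at 222 ± 34.6 and 226 ± 7.09 CPM (log2 fold change -0.02 ± 0.22, edgeR adjusted p = 0.982), and for ENSGALG00000023818.4 at 117 ± 37.99 and 121 ± 9.80 CPM (-0.04 ± 0.32, edgeR adjusted p = 0.973). ENSGALG00000009433.6 differed by 0.16 ± 0.22 (edgeR adjusted p = 0.782) and ENSGALG00000033789.2 by 0.44 ± 0.13 (edgeR adjusted p = 0.263). ENSGALG00000033212.2 had nearly the same estimate as in the other lineage, 0.79 ± 0.16, with an edgeR adjusted p of 0.21. It passed with DESeq2 (adjusted p = 0.00143), with voom (adjusted p = 0.0103) and without t0 library 1 (1.02, edgeR adjusted p = 0.00863), within a range of 0.00143 to 1 over its alternatives. Averaged over both lineages, heat raised 3 genes and lowered 0: ENSGALG00000033789.2 (0.71 ± 0.09), ENSGALG00000033212.2 (0.80 ± 0.11) and ENSGALG00000011715.5 (0.88 ± 0.15). The count of 0 depended on the t0 libraries and on the tool. Without t0 library 1 it became 213, with 141 higher and 72 lower. DESeq2 called 44 genes, 15 higher and 29 lower, and voom with quality weights 4, so that the main direction also changed.

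LPS against t0 in the non-conditioned lineage, a comparison that includes any effect of injection, handling and elapsed time, gave 175 raised and 27 lowered genes. Of the raised genes 148 changed by over 2-fold, 75 by over 4-fold and 29 by over 16-fold. Among the lowered genes 13 fell by over 2-fold and 3 by over 4-fold, these being ENSGALG00000006323.6 (log2 fold change -2.40 ± 0.61, edgeR adjusted p = 0.0356), which is outside the naming rule, and ENSGALG00000036686.1 and ENSGALG00000001177.5, below. The raised genes were of low abundance at t0, with a median of 14.5 CPM against 29.6 CPM for all genes tested, and 19 of them lay under 1 CPM. The lowered genes had a median of 66.8 CPM. ENSGALG00000028256.2 had the largest rise under the naming rule, from 0.647 ± 0.230 CPM (8 counts in 3 libraries) to 135 ± 61.7 CPM, with a log2 fold change of 7.64 ± 0.60 (edgeR adjusted p = 5.6e-08). ENSGALG00000034478.1 went from 1.45 ± 1.01 to 177 ± 43.9 CPM, by 6.80 ± 0.43 (edgeR adjusted p = 4.2e-09). The largest falls under the naming rule were those of ENSGALG00000036686.1, from 32.4 ± 1.22 to 6.98 ± 1.21 CPM (log2 fold change -2.21 ± 0.28, edgeR adjusted p = 4.3e-05), and ENSGALG00000001177.5, from 31.1 ± 2.41 to 7.21 ± 2.70 CPM (-2.11 ± 0.36, edgeR adjusted p = 0.0012). The 4 heat-raised genes were also raised by LPS, with log2 fold changes between 0.73 ± 0.12 for ENSGALG00000033789.2 and 2.24 ± 0.31 for ENSGALG00000023818.4. Heat and LPS were compared with the same 3 t0 libraries, which makes such overlaps more frequent. An effect of handling or elapsed time, common to both challenges, would do the same and was not tested. Independent lists would share 0.0884 genes, a number that leaves out the shared controls. Unchanged groups were therefore simulated 20 times against these controls. The highest number of genes called in both comparisons was 0, against the 4 observed, but few calls can arise without any change. The mean LPS change of the 4 genes was 1.40 on the log2 scale. For the 4 top heat genes of each simulation it had a mean of 0.97 and a highest value of 1.75. These top genes were taken by p alone, without a threshold or a match of abundance. Part of the excess may still come from the shared controls, which were too few to split. Against the t0 libraries of the conditioned lineage all 4 were also higher in every LPS library of the non-conditioned lineage, by 0.86 to 1.63 (edgeR adjusted p at most 0.00798). None of these libraries picked the genes. This argues against the shared controls as the whole account, though the comparison also crosses the lineages. DESeq2 called 237 genes, of which 200 were among the 202.

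In the conditioned lineage LPS raised 93 genes and lowered 8. Of the raised genes 83 changed by over 2-fold, 46 by over 4-fold and 12 by over 16-fold, and 6 of the lowered genes fell by over 2-fold. ENSGALG00000028256.2 stood at 102 ± 45.8 CPM under LPS against 7 counts in 3 libraries at t0 (log2 fold change 5.54 ± 0.65, edgeR adjusted p = 3.2e-05). All 7 counts lay in t0 library 2. Without it the t0 libraries held 0 counts of this gene and the fitted log2 fold change was 10.82, which depends on the prior count. Without t0 library 1 it was 4.796. ENSGALG00000034478.1 stood at 118 ± 50.2 CPM against 2.40 ± 2.45 (5.58 ± 0.51, edgeR adjusted p = 1.3e-06), and its log2 fold change was 6.92 without t0 library 2, 5.02 without t0 library 1 and 7.26 without t0 libraries 2 and 3. ENSGALG00000001177.5 fell by 2.20 ± 0.40 on the log2 scale (edgeR adjusted p = 0.00494, but 0.0689 without t0 libraries 2 and 3, the highest of a range from 3.4e-05), while ENSGALG00000036686.1 had a log2 fold change of -1.08 ± 0.29 outside the threshold (edgeR adjusted p = 0.0774). This gene stood at 14.8 CPM in t0 library 2 and at 31.5 and 29.3 CPM in t0 libraries 1 and 3. It passed without t0 library 2 (-1.36, edgeR adjusted p = 0.0188) and with DESeq2 (adjusted p = 0.0399), within a range of 0.0188 to 0.396 over its alternatives. Of the 4 heat-raised genes, ENSGALG00000033789.2 was raised here (0.64 ± 0.13, edgeR adjusted p = 0.00893), and ENSGALG00000023818.4 had 1.14 ± 0.32 (edgeR adjusted p = 0.0893) and passed with DESeq2 (adjusted p = 0.0237). DESeq2 called 157 genes, a fit to the compared groups only called 66, and a fit without t0 library 2 called 63. A fit without t0 libraries 2 and 3 leaves 1 t0 library, so its number of calls is not given.

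The lists of the lineages overlapped. Of the raised genes 75 were shared, where independent lists would share 2.05, and 4 lowered genes were shared, against 0.0273 (ENSGALG00000001177.5, ENSGALG00000003879.5, ENSGALG00000024449.4 and ENSGALG00000039696.2). The number of shared raised genes was 52 without t0 library 2 of the conditioned lineage. These comparisons had no libraries in common. A gene called in both lineages moved in opposite directions in 0 cases. Of the 100 genes raised past the threshold in the non-conditioned lineage alone, 95 had a positive estimate in the other, and so had 17 of the 18 genes raised past the threshold in the conditioned lineage alone. Across the 7921 genes, which are not independent replicates, the LPS responses of the lineages had a Pearson r of 0.51 and a Spearman rho of 0.19. The heat responses had an r of -0.19 and a rho of -0.19. Both depended on the filter and on single libraries. The LPS r was 0.23 without a filter, 0.65 with the stricter filter and 0.37 without t0 library 1 of the conditioned lineage. The heat r was -0.07 without a filter, -0.33 with the stricter filter, -0.30 and -0.05 without heated library 1 and 3 of the non-conditioned lineage, and 0.03 without t0 libraries 2 and 3 of the conditioned lineage.

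**Figure D3:**
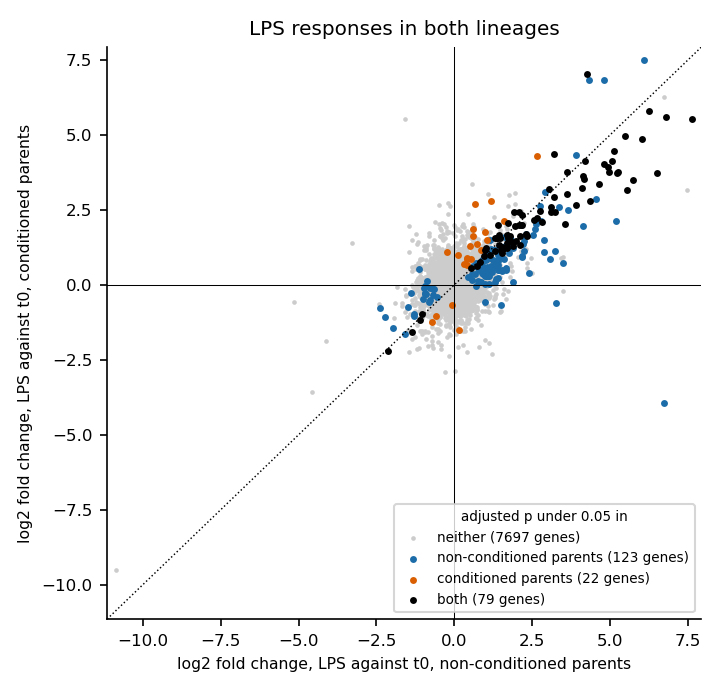
Log2 fold change of each tested gene for LPS against t0 in the non-conditioned (x axis) and conditioned (y axis) lineage, coloured by the lineage in which its edgeR adjusted p lay under 0.05; the dotted line marks equal changes. The 75 genes raised and 4 lowered in both lineages (black) lie in the upper right and lower left of the plot.

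Conditioned against non-conditioned parents at t0 asks whether parental conditioning alone left a difference in unchallenged chicks. EdgeR called 0 genes, with 1243 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.0907. The heat-raised genes did not pass with edgeR either: ENSGALG00000011715.5 differed by 0.34 ± 0.22 (edgeR adjusted p = 0.444), ENSGALG00000023818.4 by 0.61 ± 0.32 (edgeR adjusted p = 0.356), and ENSGALG00000033212.2, at 2045 ± 519 against 3167 ± 288 CPM, by -0.63 ± 0.16 (edgeR adjusted p = 0.0956, DESeq2 adjusted p = 0.0121). This count depended on the tool and on single libraries. DESeq2 called 245 genes, 179 higher and 66 lower in the conditioned lineage, and voom with quality weights 446, 262 higher and 184 lower. Without t0 library 1 of the conditioned lineage edgeR called 438, with 183 higher and 255 lower. A fit without t0 libraries 2 and 3 of that lineage leaves 1 library in the group. Its number of calls cannot show whether the calls rest on those libraries. Depth and lineage went together at t0. The first thinning to 1 total gave 1 gene. Thinning evens out the totals but not whatever made them differ, which cannot be told apart from lineage.

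Under heat, 2 genes were lower in the conditioned lineage and 0 were higher. ENSGALG00000011715.5 stood at 222 ± 34.6 CPM in the conditioned and 614 ± 166 CPM in the non-conditioned lineage (log2 fold change -1.46 ± 0.22, edgeR adjusted p = 0.0158). ENSGALG00000023818.4 stood at 117 ± 37.99 against 428 ± 156 CPM (-1.86 ± 0.31, edgeR adjusted p = 0.0355). Both belong to the 4 genes that heat raised in the non-conditioned lineage, and all 4 were lower in every heated library of the conditioned lineage than in any heated library of the other. The remaining pair did not pass, ENSGALG00000009433.6 at -1.15 ± 0.21 and ENSGALG00000033789.2 at -0.66 ± 0.12, each with an edgeR adjusted p of 0.0644. ENSGALG00000033212.2 had -0.63 ± 0.16 (edgeR adjusted p = 0.63, DESeq2 adjusted p = 0.019). With DESeq2 ENSGALG00000009433.6 and ENSGALG00000033789.2 passed (adjusted p = 0.000152 and 8.4e-05), and with voom ENSGALG00000023818.4 did not (adjusted p = 0.0669, in a range of 1.6e-06 to 0.299 over its alternatives). The 4 were picked for high values in the heated libraries of the non-conditioned lineage, which widens this difference. DESeq2 called 10 genes, 8 of them lower, and edgeR with the replicate block called 4, all lower. The count fell to 0 without heated library 1 or 3 of the non-conditioned lineage, without heated library 2 or 3 of the conditioned lineage, and in a fit to the compared groups only, while the estimate for ENSGALG00000011715.5 stayed between -1.67 and -1.30 over all alternatives.

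Under LPS, edgeR called 0 genes between the lineages (301 genes at an unadjusted p under 0.05, smallest adjusted p 0.747), and DESeq2 called 0. The 301 are fewer than a share of 0.05 of the 7921 genes tested. ENSGALG00000034478.1 stood at 118 ± 50.2 CPM in the conditioned and 177 ± 43.9 CPM in the non-conditioned lineage (-0.58 ± 0.30, edgeR adjusted p = 0.999). ENSGALG00000028256.2 differed by -0.43 ± 0.38 (edgeR adjusted p = 0.999). The genes that LPS raised on the average of both lineages, 231 in number, took 5.27% ± 0.27 of the counts under LPS in the non-conditioned and 5.03% ± 0.37 in the conditioned lineage (SD, n = 3, exact permutation p = 0.5). At t0 they took 2.32% ± 0.12 and 2.34% ± 0.06.

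**Figure D4:**
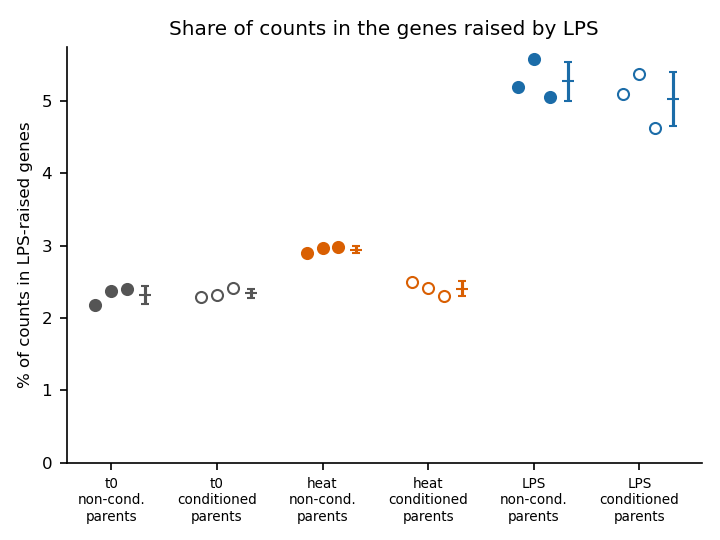
Percent of each library's counts (points) in the 231 genes that LPS raised on the average of both lineages, with mean ± SD of 3 libraries (bars). The LPS groups stand at 5.27% and 5.03%, the t0 groups at 2.32% and 2.34%, and the heat groups at 2.94% and 2.41%.

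The difference of the heat response between lineages asks for genes whose response depended on the parents. EdgeR called 0 genes (1096 at an unadjusted p under 0.05). The 2 genes that differed under heat shared the smallest adjusted p with ENSGALG00000029872.1 (-2.66 ± 0.48). The log2 difference, conditioned minus non-conditioned, was -1.80 ± 0.31 for ENSGALG00000011715.5 and -2.47 ± 0.44 for ENSGALG00000023818.4, each with an edgeR adjusted p of 0.0657. DESeq2 gave both an adjusted p of 5.1e-05, among 123 genes called, 35 positive and 88 negative. ENSGALG00000033212.2 had a difference of -0.00 ± 0.23 (edgeR adjusted p = 0.995). The count became 239 without t0 library 1 of the conditioned lineage (130 positive, 109 negative), 2 without heated library 2 of the non-conditioned lineage, 64 with voom quality weights (32 of each sign), and 3 without the low-count filter or with the compared groups only.

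For the difference of the LPS response between lineages edgeR called 0 genes (483 at an unadjusted p under 0.05, smallest adjusted p 0.445) and DESeq2 called 0. Without t0 library 1 of the conditioned lineage edgeR called 1. The estimates of the 4 genes named for LPS were -2.10 ± 1.25 for ENSGALG00000028256.2, -1.22 ± 0.90 for ENSGALG00000034478.1, 1.13 ± 0.41 for ENSGALG00000036686.1 and -0.09 ± 0.55 for ENSGALG00000001177.5, none past the threshold (edgeR adjusted p between 0.764 and 0.989). The estimate for ENSGALG00000028256.2 rests on t0 library 2 of the conditioned lineage, which held all 7 of that group's counts. Without it the response of the conditioned lineage was fitted at 10.82, above the 7.64 of the other lineage, so that the sign of this difference is not settled. The same holds for ENSGALG00000034478.1, with 6.92 in the conditioned lineage without t0 library 2 against 6.80 in the other.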

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

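The exact permutation of the set differences, the test of depth for the counts under LPS and the test of single libraries for the heat genes were chosen after the results were seen. Groups of 3 libraries are too small for a test of single outlying libraries. Of 4 tests of gene sets taken from the average of both lineages, 3 gave a difference between lineages by fry, while the smallest exact permutation p after adjustment was 0.08. The number of genes changed by LPS and the 4 genes raised by heat in the non-conditioned lineage are described beside these sets and are not part of those tests.

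The 231 genes raised by LPS had smaller estimates in the conditioned lineage, with a median difference of -0.20 on the log2 scale and 147 of 231 genes below 0. The mean difference of -0.20 had an exact permutation p of 0.04 (adjusted 0.08 over 4 tests), and fry gave an adjusted p of 0.0174. Part of it lies at t0. The mean log2 level of these genes was higher at t0 in the conditioned lineage by 0.11 (exact permutation p = 0.1, the smallest possible) and lower under LPS by -0.09 (exact permutation p = 0.4). The median difference was -0.10 without t0 libraries 2 and 3 of the conditioned lineage and -0.33 with voom quality weights, the ends of its range over the alternatives. The 59 genes lowered by LPS had a median difference of -0.00 (exact permutation p = 0.97).

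With this goes a larger number of genes changed by LPS in the non-conditioned lineage, 202 against 101, a ratio of 2. Low depth of the t0 libraries of the conditioned lineage remains an open explanation. With every library thinned to the shallowest total, the ratio was 1.49 ± 0.09 (SD over 10 thinnings), which neither reached a clear 1.5 nor stayed clearly under it. Measured against all 6 t0 libraries as a common control, the counts were 222 and 160, a ratio of 1.39, with values of 1.32 to 1.44 when 1 t0 library was left out, which leaves the t0 libraries of the conditioned lineage as an open explanation. This fit also replaced the control of the other lineage, raised the number of control libraries for both and made the comparisons share them, so that the fall of the ratio cannot be put down to those libraries alone. A weaker response of the raised genes, with the mean difference of -0.20, may account for part of the gap. That difference uses the same libraries as the counts, those of t0 included, so it is no separate test. It includes the t0 difference of 0.11 in mean log2 level, beside -0.09 under LPS alone (exact permutation p = 0.4). The contributions of depth, t0 libraries and response were not separated. Compared under LPS alone, without t0 libraries, the lineages differed in 0 genes with edgeR (301 at an unadjusted p under 0.05) and 0 with DESeq2, and the share of counts in the raised genes differed by -0.242 percentage points (exact permutation p = 0.5). An effect of parental conditioning stays open.

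The 3 genes raised by heat on the average of both lineages had differences between the lineages of -1.80 (ENSGALG00000011715.5), -0.54 (ENSGALG00000033789.2) and -0.00 (ENSGALG00000033212.2), so that the first of them weighs most. Fry gave an adjusted p of 0.00295, and the mean of -0.773 had an exact permutation p of 0.095 (adjusted 0.127). The median of -0.54 was -0.40 without t0 libraries 2 and 3 of the conditioned lineage. The 4 genes raised by heat in the non-conditioned lineage were lower under heat in the conditioned lineage by a mean of -1.28 on the log2 scale. Over 10 thinnings to 1 total the mean was -1.29 ± 0.03 (SD). Thinning hardly changes the expected ratio of genes with such counts, so it could not decide on depth. The totals of the lineages overlapped under heat. With each heated library left out in turn, the mean of these genes lay between -1.45 and -1.16. The genes were picked for high values in the non-conditioned heated libraries and kept fixed, so this tests single libraries only weakly. The number of genes called between lineages under heat fell to 0 without some of these libraries, as given above. Open explanations include a difference between birds, pens or dissections that the labels do not give. Parental conditioning itself, which may have lowered the response of these genes, is another. That response need not be to heat. LPS and heat were compared in the non-conditioned lineage, a contrast outside the comparisons fixed at the start. The 4 genes differed by -0.36 to -0.12 on the log2 scale (edgeR adjusted p at least 0.555). An effect of handling or elapsed time, common to both challenges, was not separated from heat and stays open. The genes were chosen for high values in 1 of the groups compared, so that the size of the difference is inflated.

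For the heat response of the 231 LPS-raised genes the median difference between lineages was -0.26, with 149 of 231 genes below 0 (exact permutation p = 0.04, adjusted 0.08; fry adjusted p = 0.0174). It uses the same t0 libraries as the LPS difference, with their difference of 0.11 in mean log2 level, and under heat alone the level differed by -0.13 (exact permutation p = 0.3). The median was -0.15 without heated library 3 of the non-conditioned lineage, -0.39 without heated library 1 of the conditioned lineage, -0.39 with the stricter filter and -0.38 in the first thinning.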

How the results depend on the processing

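Thinning, the deposited factors and the removal of 2 t0 libraries were chosen after the data were seen. Size factors, the stricter filter and the deposited factors left every count of changed genes within 1.5 times. DESeq2 gave 27 genes for heat in the non-conditioned lineage, 44 for heat and 157 for LPS in the conditioned lineage, 245 between lineages at t0, 10 under heat and 123 for the difference of the heat response. Voom with quality weights gave 13, 4, 446 and 64 for heat in the non-conditioned and conditioned lineage, for t0 and for the difference of the heat response. Without a filter that difference had 3 genes. With only the compared groups it had 3, LPS in the conditioned lineage 66, the lineages at t0 3 and under heat 0. The first thinning gave 1 gene at t0. Removing t0 libraries 2 and 3 of the conditioned lineage gave 39 for LPS there and turned the correlation of the heat responses to 0.0322. The cause of these changes was not tested, except that the last has 1 t0 library left, assumed to vary like the others.

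Leaving out each library in turn gave 3 to 6 genes for heat and 144 to 169 for LPS in the non-conditioned lineage, 0 to 213 and 63 to 127 in the conditioned lineage, 0 to 438 between lineages at t0, 0 to 3 under heat and 0 under LPS, 0 to 239 for the difference of the heat response and 0 to 1 for that of the LPS response. The upper ends of 213, 127, 438, 239 and 1 all came without t0 library 1 of the conditioned lineage. Of the other values recomputed, for named genes and sets, 437 kept their side, 15 lost and 8 gained the threshold, 16 moved and 1 changed sign.

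The replicate block, using the title number, gave 6, 0, 220, 119, 0, 4, 0, 0 and 0 genes in the order of the comparisons, against 4, 0, 202, 101, 0, 2, 0, 0 and 0. The labels state no bird, litter or day behind the numbers. Of 45 pairs with 1 number, 13 correlated over 0.1, in a range of -0.23 to 0.26. Of the 18 libraries, 8 correlated best with their own number. The mean r was 0.04 for pairs with 1 number and -0.02 for pairs with different numbers, a difference that was not tested. Something shared by a number is therefore not excluded. The gene list tests by camera, fry and block were not run, since no identifier has a name, and the pseudocount and quantile alternatives were not run, since the table holds counts. With every library thinned to the 828424 counts of the shallowest, LPS gave 124 to 145 genes in the non-conditioned and 85 to 102 in the conditioned lineage over 10 thinnings.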

Other observations

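The test of depth for the t0 libraries was chosen after the result was seen; the test of spread inside the challenged groups and the splits of the samples were chosen before their results were seen.

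Of the 231 genes raised by LPS, 160 had a positive heat estimate in the non-conditioned lineage, with a median log2 fold change of 0.24, and 105 in the conditioned lineage, with a median of -0.04. These counts of signs were not tested within a lineage. Their share of the counts was 2.94% ± 0.05 under heat in the non-conditioned and 2.41% ± 0.10 in the conditioned lineage (SD, n = 3). Every heated library of the first lay above every one of the second (exact permutation p = 0.1, the smallest possible, adjusted 0.4 over 12 tests). The 231 include the 4 genes raised by heat and ENSGALG00000033212.2, which stood at 5510 ± 346 against 3549 ± 414 CPM under heat. The difference in share, -0.54 percentage points, therefore repeats in large part the values of genes already given. ENSGALG00000033212.2 was also higher in the non-conditioned lineage at t0 (3167 ± 288 against 2045 ± 519 CPM). The mean log2 level of the 231 genes under heat was lower in the conditioned lineage by -0.13 (exact permutation p = 0.3). In this measure abundant genes weigh no more than others. The t0 libraries also served to pick the genes, so the estimates against t0 are raised in both lineages; the comparison of heated libraries does not use t0. Without t0 libraries 2 and 3 of the conditioned lineage the median difference of the heat response was -0.21.

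The t0 libraries 2 and 3 of the conditioned lineage stood apart from the other 16 libraries on the second component, by 3.34 and 5.14 SD of these. Low depth does not account for this, since the smaller of the distances was at least 3.72 SD in each of 10 thinnings to 1 total. A general difference between birds or dissections is a candidate explanation. The first component of the t0 libraries alone held 50.1% of their variance, and a score of the 100 genes at each of its ends was 1.98 and 3.82 in these libraries and between -1.17 and -0.60 in the other t0 libraries. Inside the heat and LPS groups the score varied with a pooled SD of 0.459, above all of 1000 random gene sets matched on expression (percentile 100, median 0.0839), from -0.78 to 0.81. The genes of the score were picked for shared variation at t0, while genes of a random set need not vary together. A high percentile was therefore likely in advance, and the test cannot decide on a general difference. The scores of the challenged libraries also stayed below the 1.98 and 3.82 of the t0 libraries to be explained. Cell composition, dissection and RNA quality could not be read without gene names, and an effect of parental conditioning on unchallenged birds stays open.

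Other splits of the same libraries bear on the counts. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. LPS gave 202 genes in the non-conditioned lineage against at most 0 in the other splits, and 101 in the conditioned lineage against at most 1. Heat gave 4 genes in the non-conditioned lineage against at most 3, and 0 in the conditioned lineage against at most 1. Between lineages the counts were 0 at t0, 2 under heat and 0 under LPS, against at most 0 in the other splits of each. For each count above 0 the real split alone, 1 of 10, gave as many genes. For each count of 0 all 10 do by construction. For the differences between lineages 100 splits were drawn, with at most 5 genes for heat and 12 for LPS in the other splits. Since the real count was 0 in both, all 100 splits give as many by construction, and this says nothing about chance.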
